A study of Xenopus laevis with 9 samples.

How the data were processed

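Expression was measured on 9 Affymetrix Xenopus laevis arrays, 3 groups of 3: control morpholino (CMO), ADAM13 morpholino (MO13) and ADAM13 morpholino with mRNA of GFP fused to the ADAM13 cytoplasmic domain (MO13_C13). Per the labels each embryo received 10 ng of morpholino, grew at 15 °C and gave cranial neural crest at stages 15 to 17. The mRNA dose is 300 pg per the sample labels and 0.5 ng per the series text, and the data cannot settle which was used. Per the labels, replicates 1, 2 and 3 of every group come from the same 3 experiments, so the replicate number pairs the arrays.

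The deposited values are log2 intensities that the authors obtained with GC-RMA in Affymetrix Expression Console, per the submitters' processing notes, with background correction, quantile normalization and one value per probe set. Versions of these tools are not given in the sources used here. In the authors' lists the arrays carry the same deposited log2 values, and the average changes are differences of group means in log2, per the file headers. The lists' values equal the value table with a largest difference of 0. Array medians ran from 4.88 to 5.07 and correlations across probe sets between arrays of one group from 0.979 to 0.991. Detection calls were not used here, so no statement separates low expression from background, and the precision is set by 3 arrays per group.

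The table holds 15491 probe sets, none of them an Affymetrix control, and all were tested. By the probe annotation 9304 carry 1 gene symbol (7531 different symbols), 195 several and 5992 none. Gene identifiers of 9227 probe sets matched the RefSeq gene table, which updated 2 symbols. No genome sequence was used. All columns of values were mapped to a sample.

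Choices of tests, samples, gene lists and alternatives were made before the data were examined, except where stated. Group means were compared with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, with all 9 arrays in one fit and group as the only term, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. A fit with experiment as a block was the foremost alternative. Arrays of one experiment did share deviations from their group means: correlations across probe sets were 0.51 to 0.73 for the 9 pairs of arrays from one experiment, and at most -0.06 for other pairs. Experiment accounted for 57.6% of the sum of squares, group for 22.5% and the rest for 19.8%. The main fit leaves this pairing out, so a gene that did not pass in it may still differ between groups.

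Genes were named by a fixed rule: all probe sets of adam33 and capn8, and per comparison the passing genes with one informative symbol and non-overlapping groups that had the largest changes (12 in each direction, and 6 between MO13_C13 and CMO), or the 8 with the smallest unadjusted p where fewer than 5 passed in a direction, and up to 4 members of each list by unadjusted p. After the data were seen the same rule was also applied to the fit with the block.

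The 20 gene lists cover cranial neural crest, neural plate border and placode, neural plate, epidermis, cement gland and hatching gland, mesoderm and muscle, notochord with endoderm and blood, calpains, ADAM and matrix metalloproteinases, cadherins, integrins and extracellular matrix, Wnt, BMP and TGF-beta, ephrins, Notch, p53 response, innate immunity, stress and immediate early genes, cell cycle and ribosomal proteins. Gene symbols whose synonyms clash with other genes were removed from the lists. Each gene was represented by the probe set with the highest mean over the 9 arrays. The .L and .S copies of a gene counted as separate genes, so list members are not all independent. Lists of at least 5 genes were tested with camera (preset correlation 0.01) and adjusted over the lists of a comparison. camera with an estimated correlation and fry were alternatives. Without the block no list was called by either, the lowest adjusted p being 0.20 and 0.22.

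Recovery was 1 minus the ratio of the MO13_C13 and MO13 changes against CMO, as a median over probe sets without adam33. It was compared with 20 simulated sets of arrays and recomputed with the selection made in 2 experiments and the measurement in the one left out. The fit was tested on simulated data with 200 changed probe sets among 15491 in 5 simulations of MO13 against CMO. Changes of log2 0.5, 1 and 2 were recovered in 0.6%, 38.2% and 73.3% of cases, with 0 false among 372 calls. The blocked fit recovered 8.7%, 66% and 87.9%, with 23 false among 563 calls. camera called 1 of 300 unchanged simulated lists and a list shifted by 0.5 in 5 of 5 simulations, and a simulated recovery of 0.5 was returned as 0.5. The simulated noise was drawn independently for each probe set. These simulations therefore do not give the rate of false calls for real lists, whose members may move together.

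Alternatives were the block, only the arrays of the compared groups, leaving out probe sets under the median brightness, quantile normalization, centring of the brighter probe sets, eBayes with trend and robust settings (in camera only the trend), array weights, no moderation, other thresholds, the mean over probe sets of a gene, and leaving out each array and each experiment. The block with each experiment left out, fry with the block, and a recovery from covariances between experiments were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.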

Results

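Cranial neural crest explants of Xenopus laevis were compared between embryos given a control morpholino (CMO), a morpholino against the metalloprotease ADAM13 (MO13), and that morpholino together with mRNA of GFP fused to the cytoplasmic domain of ADAM13 (MO13_C13). ADAM13 cleaves cell-surface proteins, and its gene is now called adam33. The adam33.L probe set averaged 3.64 (SD 0.76, log2) in the 3 CMO arrays and 4.34 (SD 0.52) in the 3 MO13 arrays. The difference of 0.70 (SE 0.38) did not pass limma's test (adjusted p = 0.832), and its sign differed between experiments (1.35, -0.72 and 1.47). A morpholino that blocks translation need not change its mRNA, so this value checks nothing about the knockdown of the protein. In MO13_C13 the same probe set averaged 10.07 (SD 0.14) and rose 53.2-fold over MO13 (log2 5.73, SE 0.38, limma adjusted p = 0.00471) and 86.4-fold over CMO (log2 6.43, adjusted p = 0.00187), in 3 of 3 experiments each. The probe set adam33.S stayed between group means of 1.43 and 1.56, under the lower quartile of every array. Where either probe set lies relative to the injected sequence is not given in the sources used here. With single arrays or experiments left out, the rise over MO13 stayed between 5.46 and 5.97, but its adjusted p was 0.0508 without MO13 replicate 1, 0.0605, 0.0564 and 0.0575 without MO13_C13 replicates 1, 2 and 3, and 1 and 0.622 without experiments 1 and 3. The rise over CMO lost its call without experiment 1 (6.18, adjusted p = 0.344) and without experiment 3 (6.2, adjusted p = 0.118).

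**Figure D1:**
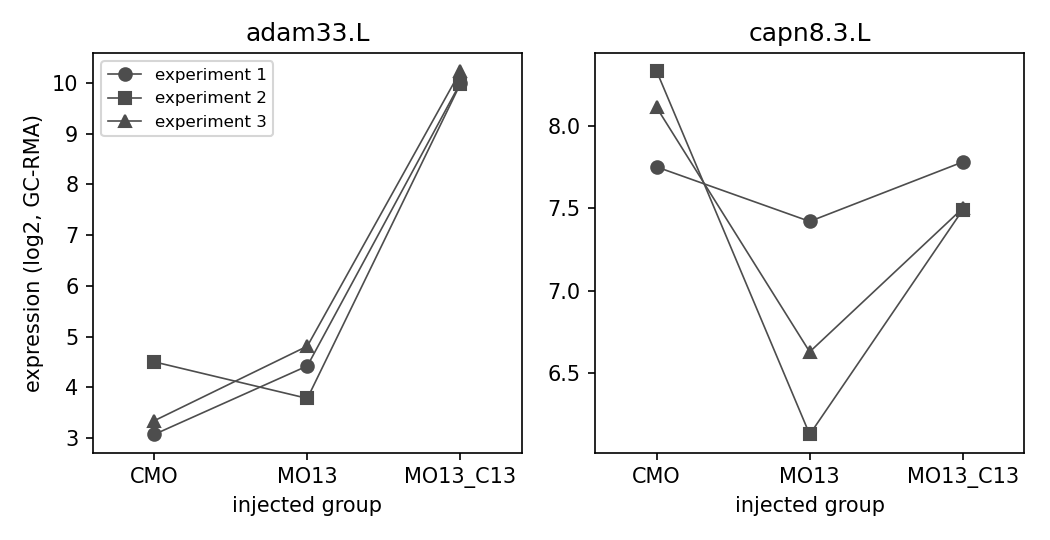
Log2 GC-RMA expression of adam33.L (left) and capn8.3.L (right) in each array by injected group; each line joins the 3 arrays of one experiment. The 3 MO13_C13 arrays of adam33.L read 10, 9.98 and 10.23, above every CMO and MO13 array, and capn8.3.L is lower in MO13 than in CMO in each experiment without passing the test over all probe sets.

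Calpain 8 is an intracellular cysteine protease. Its gene was named before the data were examined because it is known as the gene of interest of this study. Its values are therefore no independent test, also where adjusted over the list alone. The capn8.3.L probe set averaged 8.06 (SD 0.29) in CMO, 6.73 (SD 0.65) in MO13 and 7.59 (SD 0.16) in MO13_C13. It was lower in MO13 than in CMO by -1.34 (SE 0.31) and lower in 3 of 3 experiments (-0.33, -2.20 and -1.48), which did not pass over all probe sets (limma adjusted p = 0.256, and 0.0872 with experiment as a block). Adjusted over the list alone, among the 8 calpain and calpastatin genes, its adjusted p was 0.018. MO13_C13 lay 0.86 above MO13 (adjusted p = 1) and -0.47 from CMO (adjusted p = 0.891), neither passing. The rise over MO13 was seen in 3 of 3 experiments (0.36, 1.36 and 0.87, limma unadjusted p = 0.022), so MO13_C13 lay between MO13 and CMO. The fall and the rise use the same MO13 arrays with opposite signs. Chance low values in MO13 would alone give both, so the rise is no measure of recovery. The other probe set of the family, capn8.1.L, averaged 4.37, 3.76 and 4.06 and differed by -0.61 between MO13 and CMO (limma adjusted p = 0.959, and 0.132 with the block), lower in 3 of 3 experiments (-0.45, -0.61 and -0.77). Adjusted over the list alone it had 0.60 without and 0.03 with the block. Without single arrays or experiments the difference between MO13 and CMO ran from -1.84 to -0.91 for capn8.3.L and from -1.16 to -0.06 for capn8.1.L.

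The ADAM13 morpholino raised n6amt1.L, which encodes a methyltransferase of the translation termination factor, and rpn2.S, a subunit of the enzyme that puts sugars on proteins in the endoplasmic reticulum. The phosphatase gene dusp18.L and tapt1.S, a membrane protein gene linked to axial patterning, rose as well. The adaptor gene rusc1.S, the ciliary transition zone gene tmem107.L, the autophagy regulator dap.S and the helicase gene ercc3.L of the transcription factor TFIIH fell. Against CMO, n6amt1.L was 4.94-fold higher (log2 2.30, adjusted p = 0.00809), tapt1.S 3.71-fold (adjusted p = 0.0388), dusp18.L 3.28-fold (adjusted p = 0.0261) and rpn2.S 2.19-fold (adjusted p = 0.0198). On the log2 scale dap.S fell by 2.11 (adjusted p = 0.0198), rusc1.S by 2.09 (adjusted p = 0.00418), tmem107.L by 1.85 (adjusted p = 0.0064) and ercc3.L by 1.64 (adjusted p = 0.0198). Each of these 8 genes moved the same way in 3 of 3 experiments. Most had low signal. Means in CMO and MO13 were 2.81 and 5.11 for n6amt1.L, 2.68 and 4.57 for tapt1.S, and 4.59 and 2.95 for ercc3.L. They were 5.61 and 3.51 for rusc1.S, 5.60 and 3.75 for tmem107.L, and 5.66 and 3.55 for dap.S. Each of these genes thus had a group mean under the lowest array median of 4.88, while dusp18.L and rpn2.S lay above it in both groups. A further probe set of n6amt1.L differed by only 0.06, and a brighter probe set of ercc3.L (9.97 in CMO) lay 0.28 higher, so these changes belong to single probe sets. The 8 genes with the smallest unadjusted p in each direction also include some that did not pass without the block. Among these are ccdc149.S (2.28, adjusted p = 0.0574, and 0.025 with experiment as a block), the mRNA export gene nxf1.S (1.41, adjusted p = 0.0626, blocked 0.00939), the p53 target aen.L (1.18, adjusted p = 0.0792, blocked 0.0139) and the immune checkpoint gene cd276.S (-0.98, adjusted p = 0.098, blocked 0.0252). The other nxf1.S probe set differed by 0.17.

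In limma over 15491 probe sets, 15 passed between MO13 and CMO (8 higher, 7 lower), of which 9 carry a gene symbol and 6 none. At an unadjusted p under 0.05 there were 1064 where chance gives 774.6, and the 3 arrays of one group lay wholly above the other 3 for 9.9% of probe sets against 10% by chance. These chance values hold for exchangeable arrays, and arrays of one experiment resemble each other. Arrays simulated with the experiments' differences but no effect gave 172.4 probe sets and 3.6%. Their noise was drawn independently for each probe set and added to observed experiment means, which hold noise themselves. They thus overstate the differences between experiments and do not show how far counts vary when genes move together. An excess over them, here and below, is therefore no measure of effect by itself. With experiment as a block 179 passed (61 higher, 118 lower), the 15 among them, and 2546 had an unadjusted p under 0.05 against 827.05 in those simulations. The genes that passed only with the block include the kinase map2k1.L (1.57, adjusted p = 0.288 without and 0.0213 with it), the secretory pathway gene sec23ip.S (1.5, 0.236 and 0.0108), the antiproliferative gene tob1.S (1.34, 0.31 and 0.0114) and the respiratory chain gene ndufs4.S (-1.38, 0.191 and 0.0177). The rule was applied to the blocked fit only after the data were seen. The count of 15 became 4, 6 and 5 without CMO replicates 1, 2 and 3, 7, 0 and 9 without MO13 replicates 1, 2 and 3, 8, 6 and 14 without MO13_C13 replicates 1, 2 and 3, and 0 without any one experiment. Among the 8 named genes, rusc1.S and tmem107.L passed in 8 of these 12 settings and n6amt1.L in 7, the others in 1 or 2.

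Neural crest genes as a group did not pass between MO13 and CMO. Of 33 crest genes 0 passed over all probe sets and 1 adjusted over the list alone, nr2f1.L, a nuclear receptor gene, at -0.99 (adjusted p = 0.21, and 0.0257 with the block). The chemokine receptor gene cxcr4.S was lower by -1.34 (adjusted p = 0.695) and the cartilage regulator sox9.S higher by 0.43 (adjusted p = 0.704), neither passing. Of 35 mesoderm and muscle genes the troponin gene tnnt3.S passed adjusted over the list alone (-1.01, adjusted p = 0.021, and 0.0252 over all probe sets with the block), and of 19 p53 response genes ccng1.L, a cyclin induced by p53, did so (0.75, adjusted p = 0.018, blocked over all probe sets 0.0306). The stress sensor sesn2.L stood at 0.86 (adjusted p = 0.382) and gadd45g.S at -0.72 (adjusted p = 0.443), and both passed adjusted over the list alone with the block only (0.055 without it for each, 0.028 and 0.013 with it). Of 89 cell cycle genes 54 were higher, with bub3.L at 0.38 and ccna2.S at 0.78, and 35 were lower. Of the 89, 0 passed over all probe sets or adjusted over the list alone. Adjusted over the list alone, the block changed the count most for the 36 neural plate genes, from 0 to 7 higher, with hes5.2.L (0.48) and ncam1.L (0.54), and 3 lower, with tubb2b.S (-0.41). It gave 4 higher and 1 lower of the p53 list, 3 higher and 1 lower of the cell cycle list, 3 lower calpains where 1 passed without it, 1 lower BMP and 1 higher innate immune gene, and left the other lists as they were.

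Over the 20 lists between MO13 and CMO, camera called none. Closest were cell cycle and cement gland with hatching gland, both higher at adjusted p = 0.052, with 0.70 and 0.66 with an estimated correlation. The cell cycle list was called in 13 of the alternatives, among them the block (0.027), only the compared arrays (0.03), centring (0.042) and 8 with an array or experiment left out, but had 0.87 without MO13 replicate 2 and 0.66 without experiment 2. The gland list was called in 7, among them only the compared arrays (0.03), centring (0.042) and 4 with an array left out, and not with the block (0.076). Neural crest followed (lower, 0.11) with calpains and calpastatin (lower, 0.15) and stress and immediate early genes (lower, 0.35). The integrin and extracellular matrix list had 0.48. The epidermal, mesoderm and muscle, ADAM and metalloproteinase, ephrin and p53 lists had 0.49 each, and the neural plate and plate border lists 0.55 each. Notochord, endoderm and blood genes and the cadherin list had 0.61 each, ribosomal proteins 0.62, the BMP, Notch and innate immune lists 0.63 each and the Wnt list 0.72. Of the 690 list members, 0 passed limma over all probe sets in this comparison, and 28 were higher and 20 lower at an unadjusted p under 0.05. The epidermal list had a median of -0.10 and a mean of 0.01, and the BMP list a median of 0.04 and a mean of -0.06.

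Adding the cytoplasmic domain to the knockdown changed no gene but the injected one past the threshold. After adam33.L, the probe sets with the smallest p that were higher in MO13_C13 than in MO13 include the keratin gene krt19.S (0.71), the ciliary gene tekt4.S (0.60), the complement gene c9.L (1.58) and the growth factor gene fgf3.L (0.59), and among the lower ones are the kinase mok.L (-0.57) and the cargo receptor tmed2.L (-0.35), each at adjusted p = 1 and in the same direction in 3 of 3 experiments. The 4 other tmed2.L probe sets lay at -0.04, -0.11, -0.17 and -0.13, and only 1 of them was lower in every experiment. Two-sided limma called 1 probe set with and without the block, and 0 without any array of MO13_C13, without MO13 replicate 1 and without experiments 1 or 3. There were 211 probe sets at an unadjusted p under 0.05 and 1040 with the block, where exchangeable arrays would give 774.6 and the arrays of MO13 and CMO simulated without effect gave 172.4 and 827.05. The groups lay wholly apart for 4.5% of probe sets, where chance gives 10% for exchangeable arrays and those simulations gave 3.6%. Across probe sets, which are not independent replicates, the MO13_C13 minus MO13 differences of experiments 1 and 2 correlated at r = 0.36, and those of experiment 3 at -0.11 and -0.06 with them.

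Epidermal genes were higher as a group in MO13_C13 than in MO13. Of the 49 measured, 34 had higher values, among them krt19.S, tekt4.S and the tight junction gene cldn4.L (0.40), while the hyaluronan synthase has1.S was lower (-0.22). camera called the list (adjusted p = 0.00032, median 0.16), with an adjusted p = 0.20 with an estimated correlation and 0.68 with that and the block. Passing genes numbered 0 over all probe sets and 0 adjusted over the list alone in limma, with 3 higher and 0 lower at an unadjusted p under 0.05. With the block 4 passed adjusted over the list alone, tekt4.S, krt19.S, cldn6.2.S (0.61) and grhl3.L (0.54), and of the other lists only the ADAM and metalloproteinase list gained, from 1 to 2. The list median was 0.19, 0.37 and 0 in experiments 1, 2 and 3, and the call was lost without MO13_C13 replicate 2 (adjusted p = 0.21) and without experiment 2 (0.097). The other 19 lists had adjusted p from 0.53 to 0.88. Among the crest genes rgs2.L was at 0.48 and sox9.S at -0.32, neither passing. Calpains other than capn8.3.L lay on both sides of 0, with capn5.S at -0.33. In the ADAM and metalloproteinase list the median was -0.01 and the mean 0.27, since adam33.L is a member.

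With the cytoplasmic domain added, the 15 probe sets that passed between MO13 and CMO without the block all passed against CMO again. The 8 named above passed again, with n6amt1.L 4.07-fold (adjusted p = 0.0121) and rpn2.S 2.03-fold higher (log2 1.02, adjusted p = 0.031), and rusc1.S lower by -1.90 (adjusted p = 0.00355) and tmem107.L by -1.71 (adjusted p = 0.0102). The mRNA export gene nxf1.S (1.61, adjusted p = 0.031), aen.L (1.25, adjusted p = 0.0488) and the autophagy gene atg5.L (1.05, adjusted p = 0.0422) rose, and the transcription factor gene sp2.L fell by 2.15 (adjusted p = 0.0495). Of these, atg5.L and rpn2.S were outside the rule for naming genes and were chosen after their values were seen. The other nxf1.S probe set differed by 0.16 (adjusted p = 0.998), that of n6amt1.L by -0.07 and that of ercc3.L by 0.15. The genes that passed only with the block include plk2.S, a kinase induced by p53 (2.54, adjusted p = 0.473 without and 0.0408 with it), the ubiquitin ligase marchf8.L (2.28, 0.234 and 0.0114, with 2.15 and 0.80 in its other probe sets) and the kinase hipk3.L (-1.98, 0.141 and 0.0493, with -1.15 and -1.29 in its others). In limma 22 probe sets passed (12 higher, 10 lower), adam33.L among them, with 1107 at an unadjusted p under 0.05, and 272 passed with the block. The groups lay wholly apart for 12.6% of probe sets, against 10% by chance and 3.6% in the simulations of MO13 and CMO without effect. The count became 4, 5 and 3 without CMO replicates 1, 2 and 3, 6, 3 and 9 without MO13_C13 replicates 1, 2 and 3, 10 without MO13 replicate 2, 0 without experiments 1 or 3 and 1 without experiment 2. With single arrays or experiments left out, nxf1.S and aen.L passed in 0 of 12 settings (lowest adjusted p = 0.0507 each), sp2.L and tapt1.S in 1, dusp18.L in 3, dap.S, ercc3.L and n6amt1.L in 4, tmem107.L in 6 and rusc1.S in 9.

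Neural crest genes were lower and cement gland and hatching gland genes higher in MO13_C13 than in CMO. Of 33 crest genes 25 had lower values, with nr2f1.L at -0.72, the pluripotency and crest regulator foxd3.L at -0.54 and alx1.L at -0.39, and 0 passed over all probe sets or adjusted over the list alone in limma, with 0 higher and 2 lower at an unadjusted p under 0.05. With the block 1 passed over the list alone, nr2f1.L. camera called the list (adjusted p = 0.0044, median -0.18), with an adjusted p = 0.29 with an estimated correlation, and 0.36 with that and the block. fry, which tests a list for change and not against other genes, gave 0.22 without and 0.046 with the block. Of 12 gland genes 11 had higher values, and the secreted disulfide isomerase gene ag1.L (1.22, adjusted p = 0.156) passed adjusted over the list alone at 0.015. camera called that list too (adjusted p = 0.0027, median 0.50), with an adjusted p = 0.30 with an estimated correlation and 0.37 with that and the block, and its call was lost without CMO replicate 3 (0.063). The other 18 lists had adjusted p from 0.13 to 0.95. Within them, ccng1.L (1.00, over the list alone 0.0027) and sesn2.L (1.32, 0.0046) of the p53 list and tnnt3.S (-1.12, 0.01) of the muscle list passed adjusted over the list alone, with 0.0116, 0.0411 and 0.0172 over all probe sets with the block. The claudin gene cldn6.2.S (0.94, adjusted p = 0.464, blocked 0.0172) and the epidermal regulator grhl3.L (0.80, 0.633 and 0.0287) passed with the block only. Over the list alone, the block gave 6 higher and 1 lower of the p53 list, 5 higher epidermal genes, 3 higher and 1 lower of the neural plate list, 2 higher of the cell cycle and of the innate immune list, 1 higher and 1 lower of the ADAM and of the stress list, and 1 lower BMP gene.

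**Figure D2:**
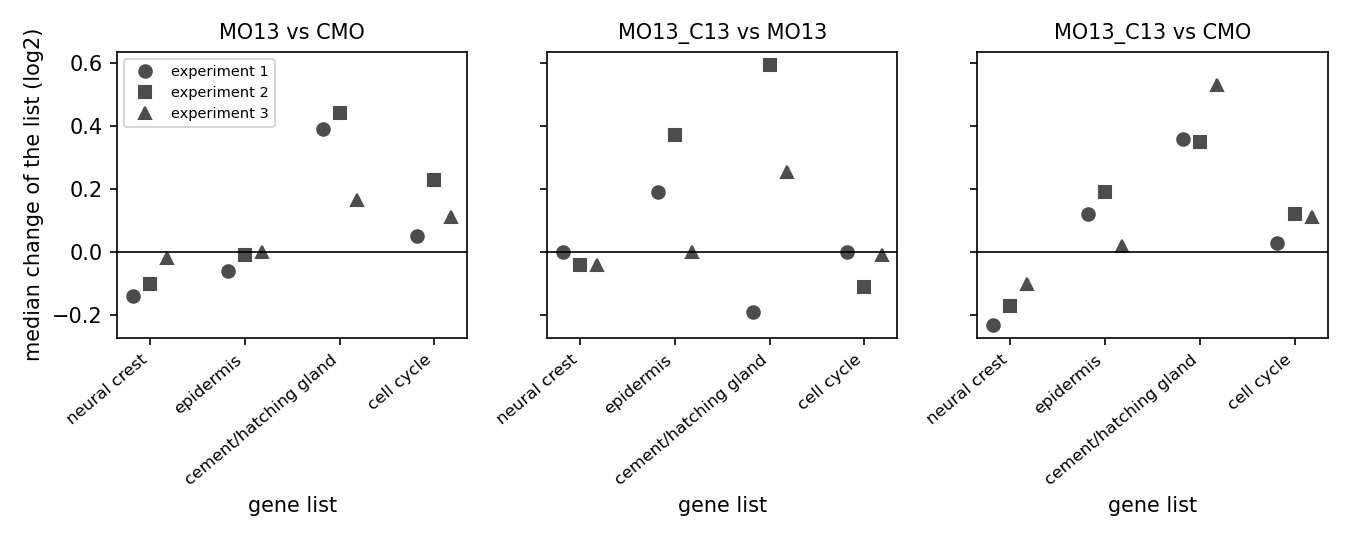
Median log2 change of 4 gene lists in each experiment, for the 3 comparisons; each marker is one experiment. Crest medians against CMO in MO13_C13 were -0.23, -0.17 and -0.10, and the epidermal medians of MO13_C13 against MO13 were 0.19, 0.37 and 0.

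Changes seen with the morpholino alone were also present when the cytoplasmic domain was added. The 15 probe sets called between MO13 and CMO, rusc1.S and n6amt1.L among them, were all called in the same direction between MO13_C13 and CMO, where independent calls would share 0.011. Simulated arrays shared 0 both with nothing changed and with both groups changed alike, so that simulation says nothing about this count. With the block 127 of 179 and 272 were shared, against 1.7 if independent, and the simulated arrays shared 0 with nothing changed and 991.85 with both groups changed alike. The comparisons use the same CMO arrays, which alone gives them a correlation across genes, 0.497 in simulated arrays without effect against 0.74 here, and a covariance of 0.018 against 0.074. Because only 15 probe sets passed, recovery was measured on the 346 with an unadjusted p under 0.01. Their median recovery towards CMO was 0.114 (0 means none, 1 complete), where simulated arrays gave 0.511 with nothing changed and 0.065 with both groups changed alike. The latter simulation changed every probe set, and 766.65 had a limma unadjusted p under 0.01 against 346 here. Its 0.065 is therefore no matched benchmark for 0.114. When probe sets were selected in 2 experiments and measured in the one left out, the median change in the direction of the knockdown was 0.60, 0.86 and 0.51 in MO13 and 0.72, 0.81 and 0.61 in MO13_C13, a mean recovery of -0.108 (SD 0.149). With selection and measurement in the same 2 experiments, recovery was 0.317 without experiment 3.

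**Figure D3:**
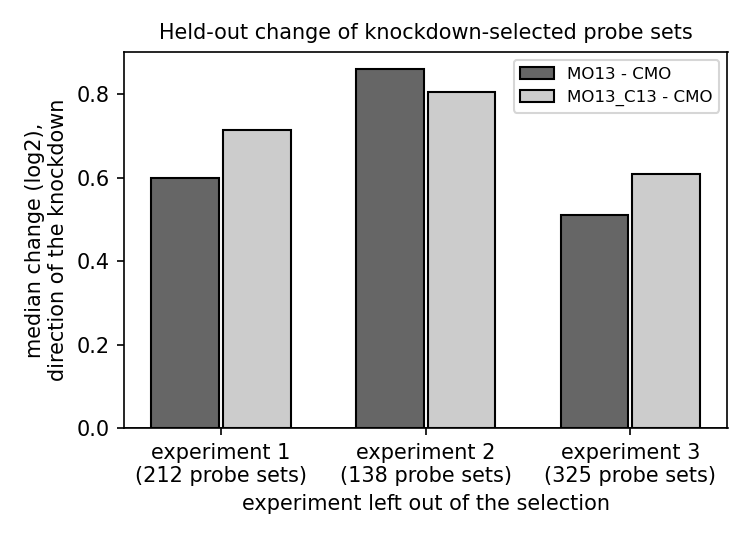
Median log2 change, in the direction of the knockdown, of probe sets selected in 2 experiments and measured in the one left out; dark bars are MO13 minus CMO and light bars MO13_C13 minus CMO. The bars stand at 0.60, 0.86 and 0.51 for MO13 and at 0.72, 0.81 and 0.61 for MO13_C13.

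The authors deposited a knockdown list of 6121 probe sets, 2982 with a positive and 3137 with a negative average log2 change, and an addback list of 2097 of these. The differences MO13 minus CMO and MO13_C13 minus MO13 have opposite signs for 1647 of the 2097 and the same sign for 450. Both use the MO13 arrays, with opposite signs, which alone gives more opposite signs, so this tally is no measure of recovery. Per the file headers the lists hold probe sets with p under 0.01. All 6121 are the probe sets whose MO13 minus CMO difference had no opposite sign among the 3 experiments, and all 2097 those for which this holds in both differences, and 0 break that rule. Of the knockdown list, 310 have an unadjusted p under 0.01 in a paired test without moderation, 346 in limma and 1035 in limma with the block. Strictly the same sign was seen for 36.4% of probe sets between MO13 and CMO, where independent signs give 25%, and for 16.9% to 22.5% after the sign of one experiment was turned. Between MO13_C13 and MO13 it was 25.7%, and 30.2% after experiment 3 was turned.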

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

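The replicate block with each experiment left out, fry with the block and the recovery from covariances were chosen after the results were seen, and the other alternatives before. Taking experiment as a replicate block raised the count between MO13 and CMO from 15 to 179 and that between MO13_C13 and CMO from 22 to 272, and left 1 between MO13_C13 and MO13. It ended no call of a named gene or list, and 38 results of named genes passed only with it. Many of these genes were named because they passed in the blocked fit, so that number is largely set by the choice. With the block and without experiment 1 the 3 counts were 0, 0 and 34, without experiment 2 they were 0, 1 and 1, and without experiment 3 they were 7, 1 and 28, where the 1 is a lower probe set and not adam33.L.

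For MO13 against CMO the count was 0 with only the 6 compared arrays, 9 without the dimmer probe sets, 8 with trend and robust settings, 2 without moderation, 346 at an unadjusted p under 0.01 and 23 at an adjusted p under 0.10. For MO13_C13 against MO13 it was 0 without moderation and 27 at an unadjusted p under 0.01. For MO13_C13 against CMO it was 9 with only the compared arrays, 34 with array weights, 3 without moderation, and 384 and 50 at those thresholds. Fewer degrees of freedom enter with only 6 arrays or without moderation, and other thresholds move counts by construction. For the filter, the trend and the array weights the cause was not tested. Quantile normalization and centring kept the counts within 1.5 times. With an array or experiment left out the counts ran from 0 to 14, 0 to 1 and 0 to 23.

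The log2 change of adam33.L ran from 5.46 to 5.97 over MO13 and from 6.15 to 6.91 over CMO when arrays or experiments were left out. The epidermal list between MO13_C13 and MO13 had adjusted p = 0.20 with an estimated correlation (0.68 with the block) and 0.49 in fry (0.39 with the block), and 5.5e-08 to 0.21 with arrays or experiments left out. Against CMO in MO13_C13, the crest list had 0.29 (0.36) and 0.22 (0.046 with the block), and 0.0033 to 0.041, and the gland list 0.30 (0.37) and 0.24 (0.099 with the block), and 0.00028 to 0.063. The gland list kept too few genes to be tested without the dimmer probe sets. In that setting the ADAM and metalloproteinase list between MO13_C13 and CMO reversed to higher, with adjusted p = 0.049, and the cause was not tested. Lists without a call gained one 38 times, 13 of them the cell cycle and 7 the gland list of MO13 against CMO, and stayed without one 1207 times.

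Median recovery moved from 0.114 to -0.108 with selection and measurement in different experiments, to 0.308 on the authors' knockdown list, whose selection uses the same MO13 arrays, and ran from 0.074 to 0.317 without single experiments. From covariances it was -0.025, but -0.059, -0.412 and 0.271 without experiments 1, 2 and 3. Selection at an unadjusted p under 0.01 is the selection already used. Low signal limits adam33.S, at 1.43 to 1.56, and no deposited value gives the background itself.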

Other observations

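The tests given here, including the counts over other splits, were chosen or their predictions written only after the results were seen. For each comparison the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and 1 of the 10, the real one, gave a count as large. The real counts were 15, 1 and 22 and the highest of the other splits 0 in every case. With the block they were 179, 1 and 272 against 0. The count of 1 is the probe set adam33.L in both fits. In the other splits any difference between the real groups widens the spread within groups and lowers the count. Their counts of 0 are therefore no measure of chance. The real split and 3 others part the arrays of every experiment, and those 3 also gave 0, while the remaining 6 keep arrays of an experiment together.

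The changes of the knockdown that remained in MO13_C13, rusc1.S and n6amt1.L among them, might come from chance values of the shared CMO arrays. Probe sets selected in 2 experiments kept a median change of at least 0.61 in MO13_C13 in the one left out, with a mean of 0.71 and SD of 0.10. This argues against chance values that are independent between probe sets and experiments. Probe sets may move together in an array and the experiments are few, so chance values shared by many probe sets are not excluded. Against a lack of injected mRNA, adam33.L was 53.2-fold higher than in MO13 and higher in every experiment. This holds if the probe set reads the injected sequence, which the sources used here do not give, and the protein was not measured. Effects of the morpholino apart from ADAM13, and functions of ADAM13 that need its other domains, may each leave the changes in place. The held-out recovery of -0.108 goes with both, and they cannot be told apart without a different morpholino or the whole protein.

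The higher epidermal list in MO13_C13 than in MO13 may come from more epidermal tissue in those explants, as a hypothesis. The 24 brighter of its 49 genes had a median change of 0.35 (0.43, 0.49 and 0.05 in experiments 1, 2 and 3), but they belong to the list whose rise raised the question, so this decides nothing. Among the brightest, krt70.S was at 0.31, krt18.1.L at 0.42 (0 in experiment 3), epcam.L at 0.28 (0 in experiment 3), has-rs.S at -0.02 and has1.S at -0.22. A lower share of crest cells among all others would raise mesoderm and endoderm genes alike. The epidermal median exceeded theirs by 0.20 on average, but by 0.24, 0.35 and 0.02 in the 3 experiments (SD 0.17), so this stays open. Weaker first bounds, for the excess 2 SE (SE 0.10), which both values passed, were replaced after they were seen by the 2 SD used in the other tests. An effect of the cytoplasmic domain on epidermal genes of the crest cells themselves was not tested.

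Of the p53 list, ccng1.L passed against CMO adjusted over the list alone in both morpholino groups, and sesn2.L in MO13_C13 (0.0046) and, with the block, in MO13 (0.028). With the block and adjusted over the list alone, 4 members passed as higher and 1 as lower in MO13, and 6 and 1 in MO13_C13. In the experiment left out, members with the same sign in the other 2 kept a median change of 0.36, 0.47 and 0.66 in MO13_C13. These medians rest on 13, 14 and 10 members, which may move together in an array. Chance values of the CMO arrays are therefore not excluded. A p53 response to the morpholino, which might follow from its sequence rather than from ADAM13, would raise the list as a whole. The list median was 0.027 between MO13 and CMO, with 11 members higher and 8 lower, which decides nothing, and the series has no different morpholino to compare.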
